A study of Homo sapiens with 33 samples.

How the data were processed

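Gene expression was measured in total RNA of 33 samples of the human ALCL lines TS and Su-DHL1 on Affymetrix HG-U133A arrays, 1 array per sample. The deposited values are MAS5 signal, an intensity per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes. MAS5 is Affymetrix's algorithm, which sets perfect match against mismatch probes and scales each array to a common target. Its version and settings are not given in the sources used here. The values themselves show the scaling: the mean after trimming 2% at each end lay between 200.06 and 200.08 on all 33 arrays, and array medians lay between 54.8 and 69.3. Because the trimmed means lay within 10% of their median, the limit set before the data were examined, the deposited values were used without further normalization. Such scaling fixes a common total per array and cannot show a global change of RNA content.

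The table held 22283 probe sets. The 68 control probe sets were left out, which left 22215, and every column of values was assigned to its sample by the labels. Gene names came from the platform annotation: 19065 probe sets had 1 gene symbol, 1043 had several and were not named, and 2107 had none there. Gene IDs of 19053 probe sets matched the human gene table of assembly GRCh38.p14, which was used for names only, and no symbol needed an update. Chromosome positions are not printed, since the array values carry no genome build. The named probe sets stood for 11963 genes.

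Signals were taken to log2 after adding 11, the 20th percentile of all values (10.8) rounded to a whole number. A probe set was kept when it reached its array's 40th percentile on at least 3 arrays of the fit. Of several probe sets of a gene that passed, that with the highest mean log2 value over the 33 arrays was used. Where further probe sets of the genes named in the text had an unadjusted p under 0.05, as the main one did, both had the same direction. The filter left 15345 probe sets and 9101 genes for the hairpin experiment, 14578 probe sets and 8594 genes for the inhibitor experiment, and 8485 genes in both.

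Groups were taken from the sample titles and descriptions. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with a mean per group, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. One fit held the 21 arrays of the 7 hairpin groups (14 residual degrees of freedom, prior degrees of freedom 8.88) and the other the 12 arrays of the 4 inhibitor groups (8 residual, 8.80 prior). P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. The comparisons were the induced against the uninduced ALK hairpin in TS cells at 84 h and 72 h and in Su-DHL1 cells at 72 h, their average, the differences between lines and between times, induced ALK hairpin against A5M, A5M against uninduced A5, A2 and A3 each against A1 and U, A1 against U, A3 against A2, and the average of A2 and A3 against A1. Samples, tests, comparisons, gene lists and the rule for naming genes were fixed before the data were examined.

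The rule named ALK, NPM1, CEBPB and BCL2A1 in every comparison. For the 2 averages and the difference between lines it took the 10 highest and 10 lowest log2 fold changes among called genes, with the same sign in each setting or inhibitor averaged, or, for the difference between lines, no overlap of induced and uninduced values in at least 1 line. For each other comparison it took the 5 highest and 5 lowest among called genes whose 2 groups of 3 did not overlap. For the difference between times, induced and uninduced values had to be without overlap at 1 or both of the 2 times. From a list it took up to 4 called members with the largest change, or, where none was called, 2 members with the largest change. Other genes are said to be chosen after their values were seen.

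The 20 gene lists, written from general knowledge, were STAT3 targets, ERK feedback and target genes, FOXO targets repressed by PI3K-AKT, G1/S and DNA replication, G2/M and mitosis, MYC and ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, ATF4 and amino acid response, BCL2 family and apoptosis regulators, T-cell receptor and T-cell identity, ALCL activation and cytotoxic markers, NF-kB targets and cytokines, interferon response, p53 targets, MHC class II, heat shock, B-cell markers, myeloid markers, and epithelial and stromal markers. Some lists share members, and CEBPB and BCL2A1, which the study picked, are members of 4 of them. Each list was tested against the other genes with limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 20 lists of a comparison. The correlation estimated from the residuals and limma's fry, which tests whether the genes of a list move one way on balance, were alternatives. A range of a list's adjusted p over the alternatives leaves out fry, which does not compare a list with other genes. Counts adjusted over the list alone use Benjamini-Hochberg over its tested members.

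The overlap of calls between experiments was tested with a one-sided Fisher's exact test. For comparisons with shared arrays, 100 simulated draws of unchanged groups gave the correlation and covariance that sharing alone produces. The interval of the difference between A3 and A2 is the 95% interval from limma's moderated statistic.

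Alternatives set in advance were an added value of 1 or 44 in place of 11, no filter, a filter at the 60th percentile, quantile normalization, every probe set tested on its own, eBayes without the trend, all 33 arrays in 1 fit, only the groups of the comparison in the fit, the replicate number as a block, A5M in place of uninduced A5 cells at 84 h, U in place of A1, a threshold of 0.01 for shared calls, the 2 other list tests, and leaving out each array in turn. Where that left an arm with fewer arrays, limma's pooled spread was used. After the data were seen, the log2 ACTB 3' to 5' ratio as a covariate and a fit without the 3 arrays of lowest agreement with their own group (uninduced A5 at 84 h replicates 2 and 3 and A5M replicate 3) were added. The latter left 1 uninduced 84 h array, which was assumed to vary like the other groups.

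The statistics were tested on simulated data with known changes, in 5 draws per comparison with 100 genes changed at each size. For TS cells at 84 h, induced against uninduced, limma on 9101 genes recovered 33.6% of changes of 0.5 and 82.6% of changes of 1 on the log2 scale, and 4.75% of its calls were false. For A2 against A1, on 8594 genes, it recovered 25.2% and 78.6%, and 6.03% of calls were false. A list shifted by 0.3 was called by camera in 5 of 5 draws of either comparison, and unshifted lists were not called. The simulated genes varied independently, so these draws cannot show how often correlated genes make camera call an unshifted list. Far fewer genes changed in the draws than were called in the real comparisons, 3699 at 84 h and 2871 for A2 against A1. The Benjamini-Hochberg cutoff depends on that number, so the shares recovered do not carry over to the real data.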

Results

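Messenger RNA was profiled in TS cells, a derivative of the Sup-M2 line, and in Su-DHL1 cells. Both are human lines of anaplastic large cell lymphoma (ALCL), a T-cell lymphoma. Both are ALK positive: they express the tyrosine kinase encoded by the anaplastic lymphoma kinase gene (ALK). The 33 Affymetrix HG-U133A arrays fell into 11 groups of 3. In 7 groups (21 arrays) the cells carried a short hairpin RNA (shRNA) that doxycycline switches on: hairpin A5 targets ALK, and A5M is a mutated control hairpin. These groups were TS cells with A5 at 84 h with and without doxycycline (1 microg/ml), TS cells with A5M at 84 h with doxycycline, TS cells with A5 at 72 h with and without doxycycline, and Su-DHL1 cells with A5 at 72 h with and without doxycycline. The other 4 groups (12 arrays) were TS cells after 6 h with compound A1, A2 or A3 at 300 nM, or without compound (U). The sample descriptions call A1 an ALK inhibitor, whereas the design text calls it the mock compound, and it is used here as the control. The descriptions call U untreated, whereas the design text speaks of control diluent. The number of arrays limits the precision of every value. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate arrays correlated at r = 0.969 to 0.985 across probe sets. Fold changes are on the log2(signal + 11) scale, which understates the change of low genes, and the ± beside them is limma's standard error with 3 arrays per group. The ± beside a signal is the SD of 3 arrays.

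The control probe sets of ACTB give a 3' to 5' signal ratio that depends on RNA quality and labelling, and it moved with some groups. In TS cells it was 1.27 ± 0.02 with the ALK hairpin at 84 h, 1.54 ± 0.05 without doxycycline and 1.52 ± 0.08 with A5M. At 72 h it was 1.32 ± 0.05 against 1.59 ± 0.11 in TS cells and 1.36 ± 0.08 against 1.39 ± 0.03 in Su-DHL1 cells. After 6 h it was 1.18 ± 0.12 in U, 1.33 ± 0.07 with A1, 1.05 ± 0.03 with A2 and 1.06 ± 0.15 with A3. For GAPDH the same ratio at 84 h, in the same order of groups, was 0.86 ± 0.03, 0.87 ± 0.06 and 0.89 ± 0.07. At 72 h the GAPDH ratio was 0.83 ± 0.03 against 0.87 ± 0.02 in TS cells and 0.86 ± 0.03 against 0.88 ± 0.02 in Su-DHL1 cells. After 6 h the GAPDH ratio was 1.00 ± 0.04 in U, 0.98 ± 0.10 with A1, 0.89 ± 0.03 with A2 and 0.94 ± 0.14 with A3.

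ALK itself, the target of the hairpin, is measured by probe sets 208212_s_at and 208211_s_at, and each was lower with the hairpin in every comparison. The signal of 208212_s_at in TS cells at 84 h was 248.0 ± 44.2 with the ALK hairpin, 2039 ± 97.2 without doxycycline and 1686 ± 46.5 with A5M. At 72 h it was 330.2 ± 52.4 against 1823 ± 19.1 in TS cells and 637.2 ± 12.3 against 2966 ± 219.3 in Su-DHL1 cells. The mean left with the hairpin was 12.2% in TS cells at 84 h, 18.1% in TS cells at 72 h and 21.5% in Su-DHL1 cells. By 208211_s_at it was 27.3%, 28.5% and 19.4%, so the 2 probe sets rank the lines in opposite order. The fall averaged over the 3 settings was 5.83-fold (log2 fold change -2.54 ± 0.06, limma adjusted p = 9.58e-20). ALK did not pass the test between A5M and A5 cells without doxycycline (-0.27 ± 0.11, limma adjusted p = 0.149), nor for the difference of the response between the lines (0.24 ± 0.15, limma adjusted p = 0.563). Yet every A5M array was below every uninduced 84 h array by either probe set. By 208211_s_at the signal was 401.8 ± 26.2 with A5M and 504.1 ± 30.1 without doxycycline. Relative to A5M, 14.7% was left with the ALK hairpin by 208212_s_at and 34.2% by 208211_s_at. Among the 6 h groups, which no hairpin targets, the signal of 208212_s_at was 3471 ± 246.2 in U, 3643 ± 593.8 with A1, 2884 ± 184.5 with A2 and 2734 ± 381.7 with A3.

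**Figure D1:**
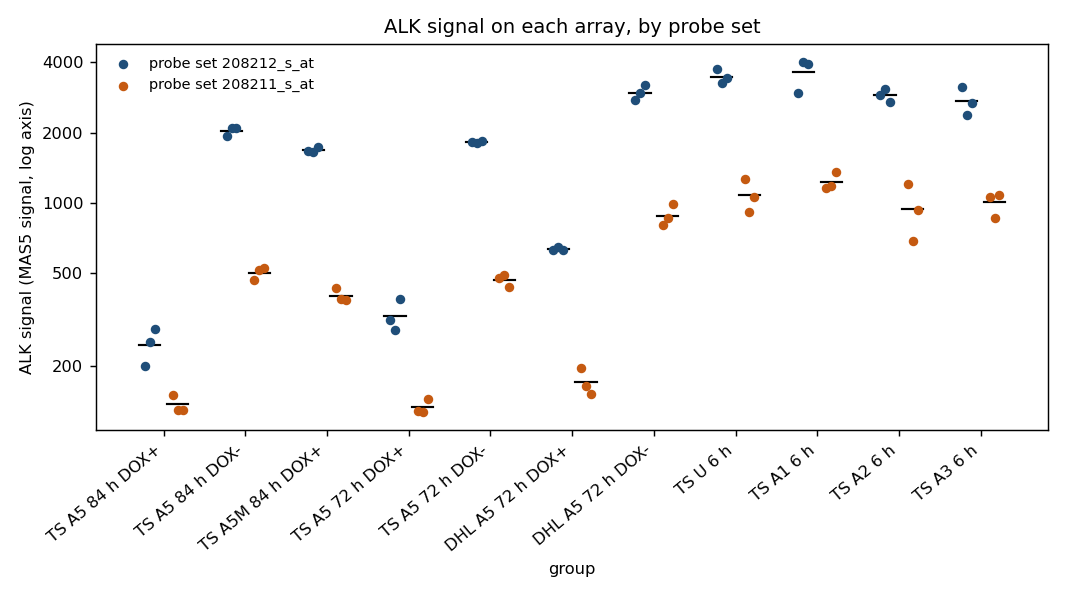
MAS5 signal of ALK on each array (points, log axis) by group and probe set, with group means as bars. The 3 groups with the induced ALK hairpin have the lowest means by either probe set, 248.0, 330.2 and 637.2 by 208212_s_at.

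The ALK hairpin was compared with its own uninduced cells in each of 3 settings, 2 of them in TS cells, and the average of the 3 differences was tested. A call on the average does not require the same sign in each setting, which the rule asked only of the genes it named. The highest average rise was in S100A4, a calcium-binding protein linked to cell motility, at 23.8-fold (4.57 ± 0.13). Other strong rises were in LAPTM5, a lysosomal membrane protein of blood cells (8.85-fold, 3.15 ± 0.07), HLA-DRA, a chain of MHC class II (8.61-fold, 3.11 ± 0.08), the G-protein-coupled receptor GPR171 (3.25 ± 0.16) and ITGB7, an integrin chain (2.93 ± 0.14). SGK1, a serine/threonine kinase, fell 11.7-fold (-3.55 ± 0.09). IL2RA, the alpha chain of the interleukin-2 receptor, fell 5.60-fold (-2.49 ± 0.07), ICOS, a T-cell costimulatory receptor, fell 5.36-fold (-2.42 ± 0.08), and UPK1B (-2.59 ± 0.06), SERPINB4 (-2.75 ± 0.11) and CALML4 (-2.76 ± 0.15) fell as well. The remaining genes that the rule selects were TRAF3IP3, SIRPG, CAPG, PHLDA1 and CLIC3 among those that rose (3.01 to 2.81), and RAD54L, GINS2 and GINS1 among those that fell (-2.49 to -2.41), besides ALK. The limma adjusted p of these 20 genes was at most 5.23e-12. CEBPB, a leucine zipper transcription factor, fell 1.60-fold (-0.68 ± 0.05), and BCL2A1, an inhibitor of apoptosis, fell 2.72-fold (-1.44 ± 0.07). The study is known to have picked both from such samples, so they are not independent evidence of a direction. NPM1, whose gene is the usual fusion partner of ALK in ALCL, fell 1.26-fold by 200063_s_at (-0.34 ± 0.04, limma adjusted p = 3.61e-07), a call that ended with the ACTB ratio as a covariate (-0.19, limma adjusted p = 0.0767). Its 2 other probe sets fell further. In TS cells at 84 h the mean signal went from 4885 to 3512 by 200063_s_at, from 4690 to 2589 by 221691_x_at and from 2564 to 1396 by 221923_s_at. At 72 h it went from 4973 to 3990, from 5017 to 3111 and from 3158 to 2031.

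The genes of DNA replication and mitosis fell together. All 38 tested members of the G1/S and replication list fell (38 adjusted over the list alone, median -1.51), among them CDC25A, a phosphatase that starts S phase (-2.38), and the helicase subunit MCM2 (-2.29). Of the 41 tested G2/M and mitosis genes 40 fell (41 adjusted over the list alone, median -1.26), including CCNA2 (-1.81), the kinase AURKB (-1.71) and the proliferation marker MKI67 (-1.66). The list of MYC and ribosome biogenesis had 31 of 35 members lower (31 adjusted over the list alone, median -0.54), such as MYC (-1.53), MRTO4 (-1.50) and NOLC1 (-1.04). The camera adjusted p was 1.91e-30 for G1/S, 1.66e-31 for G2/M and 3.66e-15 for the MYC list, and all 3 calls held with an estimated correlation, the highest adjusted p being 7.05e-04. The ACTB ratio moved with these lists in TS cells, as given above.

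Among 27 STAT3 targets 17 fell and 7 rose (18 and 7 adjusted over the list alone, median -0.59, camera adjusted p = 1.02e-06, which held with an estimated correlation). Those that fell included IL2RA (-2.49), the cytokine gene OSM (-2.04), BIRC5, which encodes survivin (-1.61), and MYC (-1.53), while the survival genes BCL2L1 (0.79) and MCL1 (0.50), named here after their values were seen, rose. Of 22 activation and cytotoxic markers of ALCL 12 fell and 8 rose (12 and 9 adjusted over the list alone, median -0.40, camera adjusted p = 0.0118, which held with an estimated correlation). IL2RA, ICOS, CCL20, a chemokine (-1.98), and TNFRSF8, which encodes CD30 (-1.61), fell, while S100A9 (1.44) and LGALS1 (1.25), likewise named after their values were seen, rose. MHC class II genes rose in 9 of 10 cases (9 adjusted over the list alone, median 1.53, camera adjusted p = 1.02e-06), with CD74, the invariant chain, at 2.64 and HLA-DRB1 at 2.27. Of 8 myeloid markers 5 rose and 1 fell as well (5 and 1 adjusted over the list alone, median 0.66, camera adjusted p = 0.0838), with ITGAX at 1.76, S100A8 at 1.49 and CSF1R at 1.31. Of 17 p53 targets 13 rose (14 adjusted over the list alone, median 0.55, camera adjusted p = 3.55e-05), such as TP53I3 (1.34), the death receptor FAS (1.17) and ZMAT3 (0.98). The MHC class II and p53 calls held with an estimated correlation. Of 14 heat shock genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 9.22e-04), with HSPE1 at -0.97 and FKBP4 at -0.71. That call was lost at adjusted p = 0.0791 with an estimated correlation. The 27 ERK feedback and target genes split into 10 that rose and 6 that fell (10 and 8 adjusted over the list alone, median 0.12, camera adjusted p = 0.763).

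Over all 9101 genes tested, limma called 4622 genes in the average, of which 2646 rose and 1976 fell. At least 2-fold changes were 299 up and 271 down. With the ACTB ratio as a covariate, an alternative added after seeing the data, the count was 2440. That ratio is partly confounded with the groups, so the covariate also costs precision.

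In TS cells at 84 h the strongest changes against uninduced cells were rises of S100A4 (6.00 ± 0.22), the chloride channel protein CLIC3 (4.19 ± 0.32), the lymphocyte surface glycoprotein CD52 (3.95 ± 0.25), SPP1, which encodes osteopontin (3.82 ± 0.09), and GPR171 (3.68 ± 0.28). SGK1 (-4.74 ± 0.15), GINS2, part of the replicative helicase (-3.93 ± 0.26), CALML4 (-3.90 ± 0.25), the chromatin remodeller HELLS (-3.89 ± 0.18) and CENPM, a centromere protein (-3.62 ± 0.16), fell most. In that comparison 38 of 38 G1/S genes and 40 of 41 G2/M genes fell (38 and 40 adjusted over the list alone), with medians of -1.97 and -2.10 (camera adjusted p = 7.80e-33 and 7.39e-40). MHC class II genes rose in 8 of 10 cases and fell in 1 (8 and 1 adjusted over the list alone, median 1.98). CEBPB (-0.63 ± 0.09) and BCL2A1 (-1.62 ± 0.11) fell. Limma called 3699 genes, 1986 higher and 1713 lower, and 1901 with the ACTB ratio as a covariate.

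Against the mutated hairpin with doxycycline, which holds the inducer constant, S100A4 (4.94 ± 0.22), SPP1 (4.33 ± 0.09), CD52 (4.10 ± 0.25) and GPR171 (3.82 ± 0.28) rose most, together with PLAC8 (3.81 ± 0.13, but 1.42 ± 0.13 against uninduced cells), and CALML4 (-4.28 ± 0.25), GINS2 (-3.77 ± 0.26), HELLS (-3.65 ± 0.18), RAD54L, a recombination factor (-3.62 ± 0.27), and CENPM (-3.39 ± 0.16) fell most. SGK1 (-3.17 ± 0.15) and CLIC3 (3.37 ± 0.32), named here after their values were seen, were not among the leading genes. G1/S genes fell in 37 of 38 cases (37 adjusted over the list alone, median -1.70) and G2/M genes in 40 of 41 (40 adjusted over the list alone, median -2.04). MHC class II genes rose in 9 of 10 cases (9 adjusted over the list alone, median 1.44, camera adjusted p = 4.32e-07, which held with an estimated correlation). CEBPB (-0.84 ± 0.09) and BCL2A1 (-1.29 ± 0.11) fell. Of the genes called, 2120 were higher and 1822 lower, 3942 in all by limma, and 2400 with the ACTB ratio as a covariate. Both 84 h comparisons share the induced arrays. They had 3004 genes called in the same direction and 22 in opposite directions. Across genes, which are not independent replicates, their log2 fold changes correlated at r = 0.899 with a covariance of 0.433. Simulated unchanged groups with the same shared arrays gave r = 0.4996 and a covariance of 0.0236. Independent lists of these sizes would share 463 higher and 343 lower genes. Part of the excess may come from the shared arrays.

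The background of the knockdown at 84 h is the comparison of A5M cells with doxycycline and A5 cells without it, which are different transduced cells. Genes of glycolysis and hypoxia were lower with A5M in 15 of 27 cases (17 adjusted over the list alone, median -0.39, camera adjusted p = 5.63e-16), and genes of the ATF4 and amino acid response were higher in 13 of 28 and lower in 1 (15 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 1.54e-10). Both calls held with an estimated correlation. ANGPTL4, a secreted regulator of lipoprotein lipase (-2.49 ± 0.21), PLAC8 (-2.38 ± 0.13), ZNF395 (-2.34 ± 0.11), DEPP1 (-2.23 ± 0.13) and NLRP3, an inflammasome sensor (-2.16 ± 0.16), fell most. ACTL8 (1.53 ± 0.27), the kinase FER (1.48 ± 0.21) and CHAC1, an ATF4 target (1.43 ± 0.23), rose. ACACA (1.73 ± 0.52) and C2CD2L (1.37 ± 0.37) also passed, but single arrays end these calls. ACACA was lost without uninduced A5 replicate 2 (0.60, limma adjusted p = 0.224) or any of the A5M replicates (highest limma adjusted p = 0.150), and C2CD2L without uninduced A5 replicate 1 or 3 or any of the A5M replicates (highest limma adjusted p = 0.121). Neither CEBPB (0.21 ± 0.09, limma adjusted p = 0.211) nor BCL2A1 (-0.33 ± 0.11, limma adjusted p = 0.0885) passed. Of 38 G1/S genes 6 were lower (7 adjusted over the list alone, median -0.16, camera adjusted p = 0.00183, which held with an estimated correlation). Camera also called 5 lists whose calls were lost with an estimated correlation. MHC class II had 5 of 10 members higher and 1 lower (6 and 1 adjusted over the list alone, median 0.42, camera adjusted p = 0.00183, and adjusted p = 0.0666 with an estimated correlation), the MYC list 6 of 35 higher (8, and 1 lower, adjusted over the list alone, median 0.19, adjusted p = 0.0666 with an estimated correlation) and heat shock 3 of 14 higher (3 adjusted over the list alone, median 0.19, adjusted p = 0.0766 with an estimated correlation). The T-cell list had 3 of 17 lower (3 adjusted over the list alone, median -0.26, adjusted p = 0.0948 with an estimated correlation), and the ALCL markers 4 of 22 lower and 2 higher (8 and 3 adjusted over the list alone, median -0.21, adjusted p = 0.0535 with an estimated correlation). The heat shock call also ended without uninduced A5 replicate 3 (0.16, adjusted p = 0.0511) and the ALCL call without A5M replicate 1 (-0.14, adjusted p = 0.0999). Limma called 636 genes, 295 higher and 341 lower. The count was 134 when only these 6 arrays entered the fit. It was 158, with ACTL8 not called (1.17, limma adjusted p = 0.135), without the 3 arrays of lowest agreement with their own group, chosen after seeing the data, which left 2 A5M arrays against 1 uninduced array assumed to vary like the other groups.

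At 72 h in TS cells S100A4 (3.999 ± 0.22), LAPTM5 (3.45 ± 0.12), DBNDD1 (3.35 ± 0.30), CDA, cytidine deaminase (3.30 ± 0.30), and PHLDA1 (3.17 ± 0.16) rose most. SGK1 (-3.90 ± 0.15), the protease inhibitor SERPINB4 (-3.85 ± 0.19), CDC25A (-2.96 ± 0.24), UPK1B (-2.74 ± 0.11) and IL2RA (-2.74 ± 0.12) fell most. G1/S genes fell in 37 of 38 cases (37 adjusted over the list alone, median -1.55) and G2/M genes in 39 of 41 (39 adjusted over the list alone, median -1.15), with camera adjusted p = 2.11e-34 and 1.47e-30. CEBPB (-0.64 ± 0.09) and BCL2A1 (-1.29 ± 0.11) fell. Limma called 3108 genes, 1724 higher and 1384 lower, and 1426 with the ACTB ratio as a covariate.

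In Su-DHL1 cells at 72 h the strongest rises were in S100A4 (3.72 ± 0.22), the lysosomal enzyme gene FUCA1 (3.25 ± 0.10), TRAF3IP3 (3.19 ± 0.19), the fucosyltransferase gene FUT7 (2.94 ± 0.20) and GPR171 (2.90 ± 0.28). OSM (-2.24 ± 0.32), the transcription factor gene ST18 (-2.22 ± 0.28), SERPINB4 (-2.11 ± 0.19) and SGK1 (-2.003 ± 0.15) fell most, besides ALK. Of 27 STAT3 targets 15 fell (17 adjusted over the list alone, with 1 that rose, median -0.62, camera adjusted p = 4.47e-12). Of 38 G1/S genes 31 fell (32 adjusted over the list alone, median -0.86), and of 41 G2/M genes 34 fell (36 adjusted over the list alone, median -0.58), with camera adjusted p = 1.07e-26 and 1.19e-20. CEBPB (-0.75 ± 0.09) and BCL2A1 (-1.43 ± 0.11) fell. NPM1 was called at -0.21 ± 0.07 by 200063_s_at (limma adjusted p = 0.0356), a call that ended without induced replicate 1 or 3 or any of the uninduced replicates (highest limma adjusted p = 0.127). Its other probe sets fell further, from 4262 ± 325.3 to 3115 ± 128.8 by 221691_x_at and from 2684 ± 42.55 to 1894 ± 112.0 by 221923_s_at. Limma called 2238 genes, 1264 higher and 974 lower.

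Whether the 72 h response differed between the lines was tested as the difference of the differences, Su-DHL1 minus TS. SPP1 rose in TS cells, from 368.3 ± 35.1 to 2735 ± 23.2, and was lower with the hairpin in Su-DHL1 cells, at 561.0 ± 40.6 against 910.6 ± 35.0 (difference -3.55 ± 0.12, limma adjusted p = 1.03e-15). S100P, a calcium-binding protein, was 412.2 ± 16.03 against 38.1 ± 6.29 in TS cells and 59.6 ± 15.2 against 59.8 ± 15.4 in Su-DHL1 cells (-3.12 ± 0.40, limma adjusted p = 3.07e-05). The response of the chemokine receptor CCR7 was higher in Su-DHL1 cells by 2.02 ± 0.20, and that of SGK1, which fell in both lines, by 1.89 ± 0.21. The fall of the cell cycle genes was smaller in Su-DHL1 cells: 15 of 38 G1/S genes differed (26 adjusted over the list alone, median difference 0.60, camera adjusted p = 1.58e-24), and 12 of 41 G2/M genes did (29 adjusted over the list alone, median difference 0.58, camera adjusted p = 8.90e-23). The rise of MHC class II genes was smaller in 4 of 10 cases (5 adjusted over the list alone, median difference -0.78, camera adjusted p = 3.30e-07). All 3 calls held with an estimated correlation. The response of CEBPB (-0.11 ± 0.13) and of BCL2A1 (-0.15 ± 0.16) did not pass as different between the lines. Limma called 263 genes, 153 higher and 110 lower. The count was 415 when only these 12 arrays entered the fit, 412 without the 3 arrays of lowest agreement, none of them from these groups, and 91 with the ACTB ratio as a covariate. Between the settings, TS and Su-DHL1 cells at 72 h had 1728 genes called in the same direction and 17 in opposite directions, with r = 0.739 and Spearman's rho = 0.669 across genes.

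**Figure D2:**
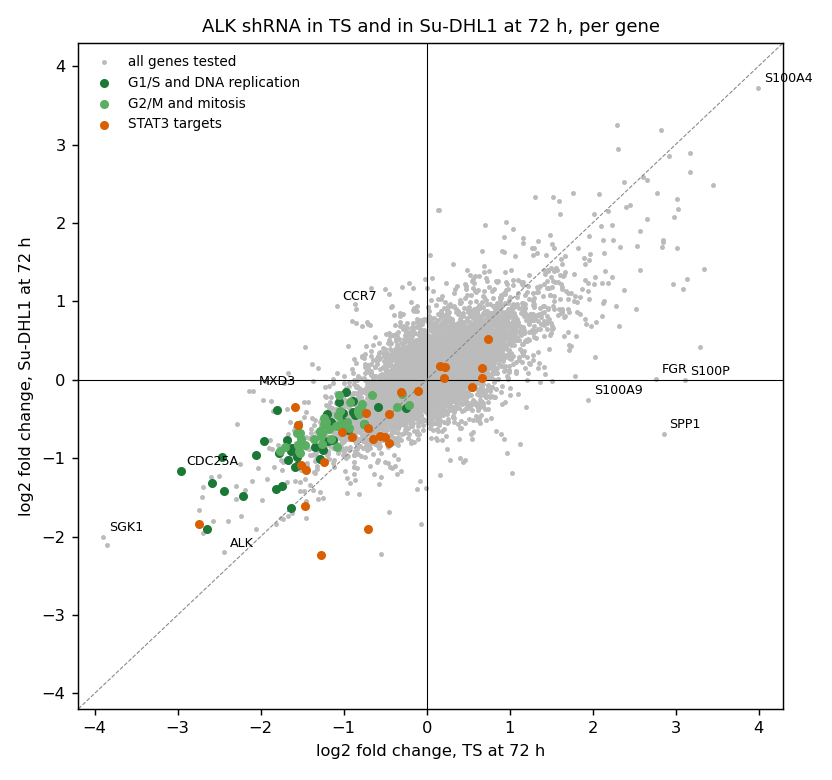
Log2 fold change with the ALK hairpin at 72 h per gene, TS cells on the x axis and Su-DHL1 cells on the y axis, with list members in colour and the line of equal change dashed. G1/S and G2/M genes lie above that line, with median differences of 0.60 and 0.58, and SPP1 lies at opposite signs.

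Between 72 h and 84 h in TS cells, the mitotic genes showed the clearest difference: 27 of 41 G2/M genes were lower in the 84 h response (39 adjusted over the list alone, median difference -0.94, camera adjusted p = 1.94e-59). G1/S genes were lower in 7 of 38 cases (15 adjusted over the list alone, median difference -0.44, camera adjusted p = 5.32e-12), and both calls held with an estimated correlation. CENPM (-2.39 ± 0.22), HELLS (-2.13 ± 0.25) and the kinetochore motor CENPE (-1.95 ± 0.25) had the most negative differences. S100A4 (1.9997 ± 0.31), SERPINB4 (1.57 ± 0.27) and FZD1, a Wnt receptor (1.26 ± 0.23), were higher. The call of SERPINB4 ended when only these 12 arrays entered the fit (1.57, limma adjusted p = 0.0601). CEBPB (0.01 ± 0.13) and BCL2A1 (-0.33 ± 0.16) did not pass, nor did ALK (-0.56 ± 0.15, limma adjusted p = 0.0795). ALK was called without induced 84 h replicate 3 (-0.67, limma adjusted p = 0.0230) or induced 72 h replicate 2 (-0.65, limma adjusted p = 0.0453). The ALK signal left was 12.2% at 84 h and 18.1% at 72 h by 208212_s_at, and 27.3% and 28.5% by 208211_s_at. A deeper knockdown at 84 h, or a difference between the samples of the 2 times, cannot be told apart from the longer time. Limma called 116 genes, 27 higher and 89 lower, and 76 without the mean-variance trend. Both times shared 2599 calls in the same direction and 2 in opposite directions (r = 0.858, Spearman's rho = 0.768 across genes).

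The ALK inhibitors A2 and A3 were compared with A1 at the same dose and time, and the average of the 2 differences was tested. MYC fell 102-fold (-6.68 ± 0.20), from a signal of 2590 ± 163.6 with A1 to 22.4 ± 15.7 with A2 and 9.93 ± 2.50 with A3. The chemokine gene CCL20 fell 55.2-fold (-5.79 ± 0.13), from 901.7 ± 48.1 to 5.87 ± 3.04 and 5.40 ± 1.31. For both genes the inhibited signal was near the added 11 and sets the size of the fold. CEMIP (-4.43 ± 0.11), DUSP6, a phosphatase that acts on ERK (-4.32 ± 0.23), the growth factor gene HBEGF (-4.31 ± 0.21), SOCS3 (-4.10 ± 0.26), IL10 (-4.07 ± 0.23), CD300A (-3.43 ± 0.10), the ribosome assembly gene RRS1 (-3.38 ± 0.25) and SOCS1 (-3.25 ± 0.18) also fell. TXNIP, an inhibitor of thioredoxin, rose 10.4-fold (3.38 ± 0.11), and CCR7 (2.66 ± 0.10), MXD3, of the MYC and MAX network (2.61 ± 0.17), BAMBI (2.43 ± 0.11), the histone gene H2AC6 (2.38 ± 0.11), ID3 (2.29 ± 0.18), CCNG2 (2.26 ± 0.20), RIN2 (2.07 ± 0.15) and S100A4 (2.07 ± 0.22) rose. MECOM was called at 2.06 ± 0.26, but with no filter on low values another probe set stands for it and the call was lost (0.02). The limma adjusted p of these 20 genes was at most 6.81e-06. CEBPB fell 2.84-fold (-1.51 ± 0.09), from 4879 ± 198.4 to 1710 ± 154.1 and 1716 ± 112.7, and BCL2A1 fell 8.15-fold (-3.03 ± 0.17). NPM1 did not pass (-0.13 ± 0.12, limma adjusted p = 0.406). ALK mRNA was called lower by 1.29-fold (-0.37 ± 0.11, limma adjusted p = 0.0175). The call was lost without A1 replicate 2 (-0.29, limma adjusted p = 0.101), without A1 replicate 3 (-0.30, limma adjusted p = 0.0985) and with the ACTB ratio as a covariate (-0.24, limma adjusted p = 0.441).

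Of 23 ERK feedback and target genes 20 fell (20 adjusted over the list alone, median -2.16, camera adjusted p = 1.30e-18), among them MYC, DUSP6, HBEGF and DUSP2 (-3.23). STAT3 targets fell in 21 of 26 cases and rose in 1 (21 and 1 adjusted over the list alone, median -1.51, camera adjusted p = 4.85e-16), with MYC, SOCS3, IL10 and SOCS1 among those that fell. Genes of MYC and ribosome biogenesis fell in 28 of 35 cases (30 adjusted over the list alone, median -0.998, camera adjusted p = 6.65e-19), including MRTO4 (-2.55) and NOP16 (-2.34). Of 22 ALCL activation and cytotoxic markers 13 fell and 3 rose (13 and 4 adjusted over the list alone, median -0.64, camera adjusted p = 2.59e-05), with ICOS (-3.13), TNFRSF8 (-3.05) and the perforin gene PRF1 (-3.04) among those that fell. These 4 calls held with an estimated correlation. MYC is in the STAT3, ERK and MYC lists, so the lists are not independent.

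G2/M genes rose: 33 of 41 were higher after 6 h (36 adjusted over the list alone, median 0.57, camera adjusted p = 1.33e-12, which held with an estimated correlation), such as the phosphatase CDC25C (1.41), NUSAP1 (1.16), DLGAP5 (1.11) and CENPE (1.06). G1/S genes were mixed, with 12 of 38 higher and 6 lower (12 and 6 adjusted over the list alone, median 0.22, camera adjusted p = 0.303). Of 28 genes of the ATF4 and amino acid response 15 fell and 1 rose against A1 (15 and 2 adjusted over the list alone, median -0.42, camera adjusted p = 4.45e-04, which held with an estimated correlation), with the amino acid transporters SLC1A5 (-2.05) and SLC7A5 (-1.91) among them. Against U the median of this list was 0.056 (camera adjusted p = 0.495). The ACTB ratio was lower with A2 and A3 than with A1, as given above, while these lists moved.

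Limma called 3286 of 8594 genes in the average, 1883 higher and 1403 lower, of which 232 and 370 changed at least 2-fold. With the ACTB ratio as a covariate it called 1544. A2 against A1 gave 2871 genes (1642 higher, 1229 lower) and A3 against A1 gave 2808 (1588 higher, 1220 lower), which became 1354 and 1452 with that covariate. Against U the counts were 3017 for A2 (1697 higher, 1320 lower) and 2893 for A3 (1615 higher, 1278 lower). In these 4 comparisons MYC fell (-6.40, -6.96, -6.47 and -7.04, each ± 0.23) and TXNIP rose (3.40, 3.37, 3.99 and 3.97, each ± 0.13). CEBPB fell (-1.51, -1.50, -1.42 and -1.42, each ± 0.10), and so did BCL2A1 (-3.04, -3.02, -2.83 and -2.81, each ± 0.20). G2/M genes rose in 34, 27, 36 and 30 of 41 cases (40, 31, 39 and 33 adjusted over the list alone), with medians of 0.68, 0.45, 0.74 and 0.55. ALK passed only for A3 against A1 (-0.41 ± 0.13, limma adjusted p = 0.0248), a call that ended without A1 replicate 2 or 3, or without A3 replicate 2 or 3 (highest limma adjusted p = 0.113). That call was also lost with the ACTB ratio as a covariate (-0.28, limma adjusted p = 0.380). Some alternatives called ALK elsewhere. After quantile normalization it passed for A2 against A1 (-0.29, limma adjusted p = 0.0380) and A3 against U (-0.40, limma adjusted p = 0.00617), as it did with all 33 arrays in 1 fit.

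The background of the inhibitors is A1 against U. The ATF4 and amino acid response list was higher with A1: 2 of its 28 members were called (21 adjusted over the list alone, median 0.46, camera adjusted p = 4.14e-31, which held with an estimated correlation). Those 2 genes were SLC7A11, the cystine transporter (1.15 ± 0.19, limma adjusted p = 0.0413), and PSAT1, an enzyme of serine synthesis (0.79 ± 0.13, limma adjusted p = 0.0413). LRRC61 was lower (-0.84 ± 0.12, limma adjusted p = 0.0300), and limma called no further genes. The count of 3 rests on single arrays. It was 0 without U replicate 2, A1 replicate 1 or A1 replicate 3 and 1 without U replicate 1 or 3, although limma's unadjusted p was under 0.05 for 767 genes with all 6 arrays. CEBPB (0.09 ± 0.10), BCL2A1 (0.21 ± 0.20) and ALK (0.06 ± 0.13) did not pass.

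A3 and A2 were compared at the same 300 nM and 6 h. Limma called 13 genes, 5 higher with A3 and 8 lower. HSD17B3, a steroid dehydrogenase gene with a signal near the added 11 in A2, was higher by 1.60 ± 0.30 and the transcription factor gene KLF2 by 0.73 ± 0.13, with CCDC92 (0.79), OXLD1 (0.65) and HPCAL1 (0.59). CEP43 (-0.90 ± 0.12), PPM1B (-0.85 ± 0.14), SPC25 (-0.80 ± 0.15), RBM12 (-0.77 ± 0.14) and GSPT1 (-0.69 ± 0.12) were lower, and the limma adjusted p of these 10 genes lay between 0.0137 and 0.0398. The count was 0 without A2 replicate 1 or 3 or A3 replicate 1 or 3, 1 without A2 replicate 2 and 8 without A3 replicate 2, and limma's unadjusted p was under 0.05 for 762 genes with all 6 arrays. For CEBPB the difference was 0.01 with a 95% interval of -0.21 to 0.22, and for BCL2A1 it was 0.02 (-0.40 to 0.44). Over the 8594 genes the interval lay within ±1 for 8026 (93.4%) and within ±0.5 for 4118 (47.9%). Of the 602 genes that changed at least 2-fold in the inhibitor average, 4 were called between A2 and A3. G2/M genes were lower with A3, by a median of -0.15 (camera adjusted p = 1.27e-07, and adjusted p = 0.0401 with an estimated correlation). Of its 41 members limma called 0 over all genes and 2 adjusted over the list alone, with 10 at an unadjusted p under 0.05. For G1/S genes the median was -0.16 (camera adjusted p = 5.47e-06), a call lost at adjusted p = 0.0562 with an estimated correlation. Of its 38 members limma called 0 over all genes and 2 adjusted over the list alone, with 9 at an unadjusted p under 0.05. A2 and A3 against the shared A1 arrays had 2288 genes called in the same direction and 1 in the opposite, with r = 0.921 and a covariance of 0.319 across genes, where simulated unchanged groups gave 0.498 and 0.0228. Independent lists of these sizes would share 303 higher and 174 lower genes. With separate controls, A2 against A1 and A3 against U, the same direction held for 2100 genes and the opposite for 3, with r = 0.858 and a covariance of 0.305.

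**Figure D3:**
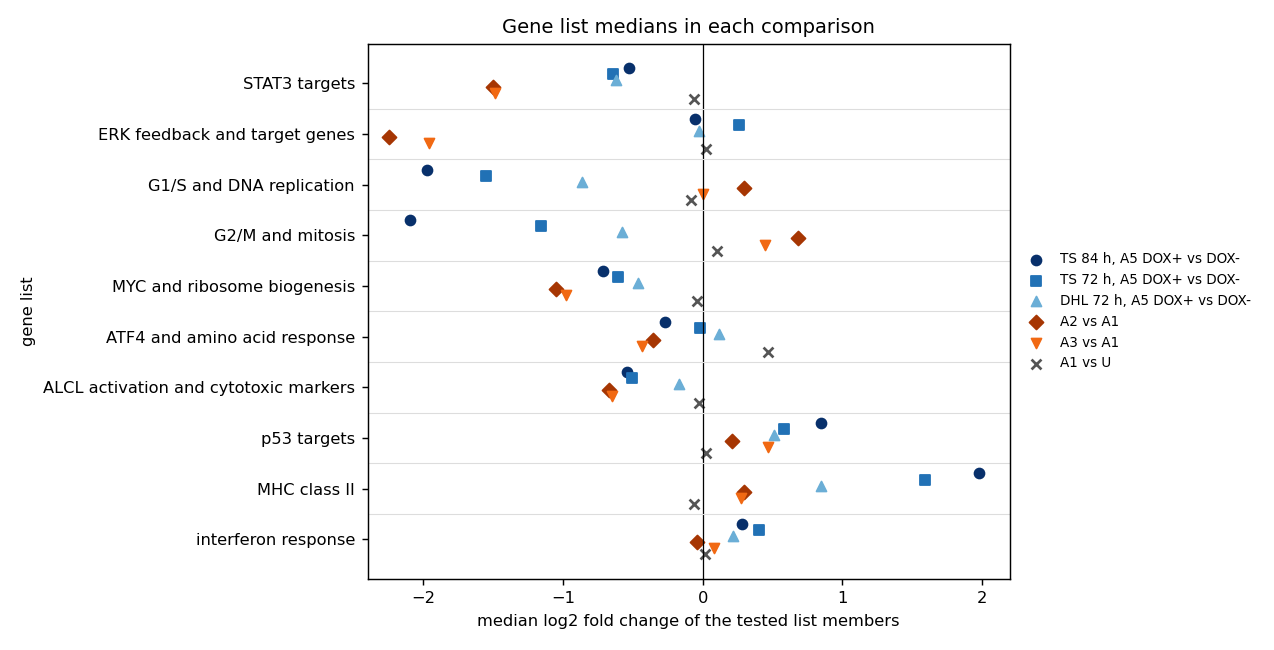
Median log2 fold change of the tested members of 10 gene lists (x axis) in 6 comparisons (symbols). G2/M genes were lower with the ALK hairpin, with medians of -2.10, -1.15 and -0.58, and higher with A2 and A3, at 0.68 and 0.45, while the ATF4 list was higher in A1 than in U, at 0.46.

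Knockdown and inhibition were set side by side because the series seeks an ALK signature, and the 2 experiments share no array. The hairpin average holds TS cells at 84 h and 72 h and Su-DHL1 cells at 72 h, and the inhibitor average TS cells at 6 h alone. Of 8485 genes tested in both, 1027 rose and 787 fell in both, 1814 in all, where independent lists would share 558 and 322 (one-sided Fisher's exact test, p = 5.05e-149 and 4.92e-198, genes not being independent). Another 502 genes were called in opposite directions, against 848 for independent lists. The log2 fold changes correlated at r = 0.333 and Spearman's rho = 0.360 across genes. By list, 25 of 35 genes of MYC and ribosome biogenesis fell in both. Of 26 STAT3 targets 15 fell in both, while 4 rose with the hairpin and fell with the inhibitors and 1 did the reverse. Of 22 ALCL markers 10 fell and 3 rose in both, and 3 rose with the hairpin and fell with the inhibitors. Of 16 p53 targets 7 rose in both, and 3 rose with the hairpin and fell with the inhibitors. CEBPB, BCL2A1, ICOS, CCL20, OSM and SOCS3 were among the genes that fell in both, and S100A4 and TXNIP among those that rose in both. Of 41 G2/M genes 32 fell with the hairpin and rose with the inhibitors, and 12 of 38 G1/S genes did so, while 6 G1/S genes fell in both. Of 23 ERK targets 8 rose with the hairpin and fell with the inhibitors, while 6 fell in both. The shared count was 635 with the ACTB ratio as a covariate.

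**Figure D4:**
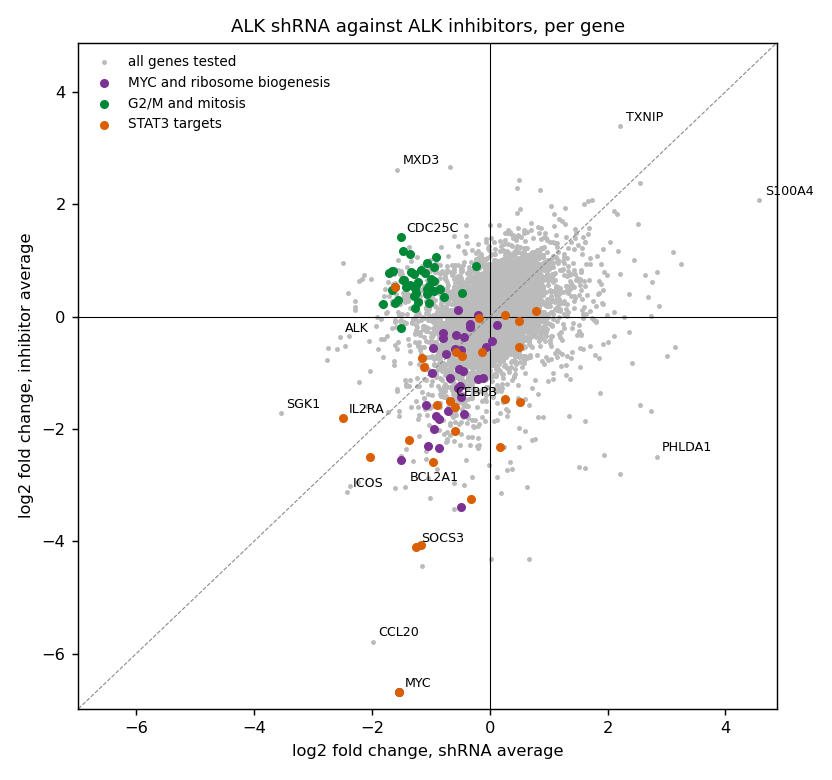
Log2 fold change per gene, the ALK hairpin average on the x axis and the inhibitor average on the y axis, with list members in colour and the line of equal change dashed. Genes of the MYC and STAT3 lists lie mostly at lower left, with 25 of 35 and 15 of 26 called lower in both, and G2/M genes at upper left, 32 of 41 being called in opposite directions.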

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

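The comparisons and list tests here were set before the data were examined, and the tests that weigh explanations of the cell cycle genes were chosen after the result was seen. Differences between the lines at 72 h and between the times in TS cells were tested with limma for genes and camera for lists.

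The response to the ALK hairpin differed between Su-DHL1 and TS cells for 263 genes, and between 84 h and 72 h in TS cells for 116. For each count, 1 of the 100 exchanges of arrays between the settings gave as many genes, the real one. The highest of the others gave 2 genes between the lines and 3 between the times. A chance assignment of these arrays is therefore excluded at 0.05. Chance differences between cultures are not, since the labels do not say that replicates are separate cultures.

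The fall of the cell cycle genes was smaller in Su-DHL1 cells, with median differences of 0.60 for G1/S and 0.58 for G2/M. With the ACTB ratio as a covariate the smaller of the 2 medians was 0.53 (camera adjusted p = 4.12e-15, and between 1.97e-25 and 5.41e-05 over the alternatives for G2/M). The slope of that covariate comes from the scatter within groups, so it cannot exclude RNA quality that differs between the groups. Low signals are argued against, as the smaller median was 0.61 with an added value of 1 (camera adjusted p = 1.46e-22). A weaker knockdown in Su-DHL1 cells cannot be told apart from a difference between the lines: relative to TS, the response was 0.54 ± 0.02 for the cell cycle lists and 0.72 ± 0.14 for STAT3 targets, a difference of 0.18 ± 0.14 (SE over genes). The spread of the STAT3 genes, ALK probe sets that rank the lines in opposite order, and the unknown shape of each response to the ALK level keep it open, although the MYC list responded at 0.77 ± 0.04, and a biological difference between the lines was not tested.

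ERK feedback and target genes had a median difference between the lines of -0.39 (0 higher and 6 lower of 27, 3 and 9 adjusted over the list alone, camera adjusted p = 5.63e-05, and adjusted p = 0.0288 with an estimated correlation, between 7.28e-06 and 0.0288 over the alternatives). MHC class II had -0.78, as in the report. For the MYC list the median was 0.14, with 0 of 35 members called by limma (camera adjusted p = 0.0312, and adjusted p = 0.249 with an estimated correlation, between 0.0110 and 0.249 over the alternatives). That call ended without TS uninduced replicate 2, Su-DHL1 induced replicate 2 or Su-DHL1 uninduced replicate 2. The T-cell list had 0.21 (3 of 17 higher, 3 adjusted over the list alone), the ALCL list 0.14 (5 higher and 1 lower of 22, 5 and 1 adjusted over the list alone) and the myeloid list -0.31 (0 higher and 1 lower of 8). Each had a camera adjusted p = 0.0498, and each call was lost with an estimated correlation, at adjusted p = 0.241, 0.0972 and 0.101. Over the alternatives the adjusted p lay between 0.00318 and 0.241, 0.0312 and 0.104, and 0.0184 and 0.159. The T-cell call also ended without TS induced replicate 2 or 3, TS uninduced replicate 2 or 3, Su-DHL1 induced replicate 1, or Su-DHL1 uninduced replicate 1 or 2, with a median of 0.02 without TS induced replicate 2. The ALCL call ended without TS induced replicate 1 or 3, TS uninduced replicate 2 or 3, Su-DHL1 induced replicate 2, or Su-DHL1 uninduced replicate 2 or 3 (lowest median 0.06). The myeloid call ended without TS induced replicate 1 or 3, TS uninduced replicate 2 or 3, Su-DHL1 induced replicate 2 or 3, or Su-DHL1 uninduced replicate 2 or 3 (median closest to 0, -0.15).

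Among single genes, the response was higher in Su-DHL1 cells for CCR7 (2.02), CAV1 (2.02), DDC (1.9996), MXD3 (1.95), F3 (1.91), SGK1 (1.89), ME1 (1.89), CDC25A (1.80), SERPINB4 (1.75) and SKA1 (1.72). It was lower for SPP1 (-3.55), S100P (-3.12), CDA (-2.88), FGR (-2.76), S100A9 (-2.21), DUSP4 (-1.95), DBNDD1 (-1.94), CLIC3 (-1.93), RRAGD (-1.90) and ASGR2 (-1.86). The call of CAV1 ended without any single one of the 12 arrays, and with no filter another probe set stands for it (1.01, limma adjusted p = 0.524, and between 7.50e-06 and 0.524 over the alternatives). That of F3 ended without any array except replicate 3 of the Su-DHL1 groups, and that of RRAGD without any array except TS uninduced replicate 1 and Su-DHL1 induced replicate 3. The call of CLIC3 ended without Su-DHL1 uninduced replicate 1 (-1.52, limma adjusted p = 0.0512, and between 0.00116 and 0.118 over the alternatives). With an added value of 44 the difference of SERPINB4 was 0.47 and not called. With an added value of 1 the calls of CAV1 (3.11), F3 (2.97), DBNDD1 (-1.92), CLIC3 (-2.69) and RRAGD (-2.34) ended. With the ACTB ratio as a covariate the calls of CAV1 (1.98), F3 (1.77), DUSP4 (-1.67), DBNDD1 (-1.47), CLIC3 (-2.38) and RRAGD (-1.94) ended.

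Between the times, the median differences, 84 h minus 72 h, were -0.44 for G1/S, -0.94 for G2/M, -0.25 for the ATF4 list and 0.30 for MHC class II. As in the report, a deeper knockdown at 84 h cannot be told apart from the longer time. The ATF4 list had 0 members higher and 1 lower (4 lower adjusted over the list alone, camera adjusted p = 7.74e-04, and adjusted p = 0.0489 with an estimated correlation, between 1.27e-04 and 0.0489 over the alternatives). MHC class II had 1 higher (2 adjusted over the list alone, camera adjusted p = 0.00936), and its call was lost at adjusted p = 0.166 with an estimated correlation and without uninduced 84 h replicate 1 (0.24, adjusted p = 0.0746, and between 3.44e-04 and 0.166 over the alternatives). PLBD1 (2.03), S100A4 (1.9997), SERPINB4 (1.57), FZD1 (1.26) and YKT6 (1.19) were higher at 84 h, and CENPM (-2.39), HELLS (-2.13), CENPE (-1.95), ZNRD2 (-1.73) and ERCC6L (-1.62) were lower. The call of PLBD1 ended without any array except uninduced 84 h replicate 3, induced 72 h replicate 1 and uninduced 72 h replicate 3. That of YKT6 ended without induced 84 h replicate 2, uninduced 84 h replicate 2, induced 72 h replicate 1, or uninduced 72 h replicate 1 or 3, and that of ZNRD2 without uninduced 84 h replicate 1 or 2 or any 72 h array. SERPINB4 was not called when only the 12 arrays of both times entered the fit (1.57, limma adjusted p = 0.0601, and between 1.04e-04 and 0.0601 over the alternatives). SERPINB4, YKT6, ZNRD2 and ERCC6L were not called without the 3 arrays of lowest agreement, which left 1 uninduced 84 h array assumed to vary like the other groups.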

How the results depend on the processing

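The ACTB ratio as a covariate and the fit without the 3 arrays of lowest agreement were chosen after seeing the data, and all other alternatives before. Of 203 named gene results called, 167 were called under every alternative and 0 of 231 reversed. Of 111 list results called, 77 were, fry included, and 1 of 300 list results reversed: the ATF4 list in the inhibitor average, at 0.056 with U in place of A1. Most named genes were picked as the most extreme calls of the main fit. Their share therefore says little about how the other calls depend on the processing. Counts of genes called moved by over 1.5 times in these cases, and the cause was not tested unless given.

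With every probe set tested on its own, which raises the number of tests and of units counted, limma called 5775 for the ALK hairpin in TS at 84 h, 6075 against A5M, 4746 at 72 h, 7324 in the hairpin average, 418 between the lines, 4608 for A2 and 4555 for A3 against A1, 4936 and 4743 against U, 5340 in the inhibitor average and 2763 shared. It gave 6 for A1 against U and 6 for A3 against A2. With the ACTB ratio as a covariate, which is partly confounded with the groups and so costs precision, the counts were 1901 at 84 h, 2400 against A5M, 1426 at 72 h, 2440 in the hairpin average, 91 between the lines, 1354 for A2 and 1452 for A3 against A1, 1544 in the inhibitor average and 635 shared, with 0 for A1 against U and 7 for A3 against A2. Whether lost precision or changed estimates lowered these counts was not tested. With fewer arrays in the fit, only the groups compared, A5M against uninduced A5 gave 134 (32.1% higher, against 46.4%), the lines 415, and limma called 0 genes for A1 against U and 0 for A3 against A2, which with all arrays of the experiment have 767 and 762 genes at an unadjusted p under 0.05. Without the 3 arrays, A5M against uninduced A5 gave 158, with 1 uninduced array assumed to vary like the other groups, and the lines, which lost no array, 412. With all 33 arrays in 1 fit, A1 against U gave 36 and A3 against A2 gave 33. Without a filter these gave 0 and 3, and after quantile normalization A1 against U gave 1. Without the trend, the time difference gave 76 and A3 against A2 gave 1. With 44 added, 33.9% of the calls between the times were higher, against 23.3%.

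The replicate block moved the count of A3 against A2 to 1 and no other by over 1.5 times. The replicate numbers do not pair the samples: of 33 pairs of same-numbered arrays 2 correlated over 0.1 (r = -0.206 to 0.108), and in 7 of the pairs the same number correlated above the other numbers. Arrays of unlike number reached r = 0.331 (U replicate 3 with an A1 array), 0.257 (U replicate 1 with an A1 array) and 0.143 (Su-DHL1 induced replicate 1 with an uninduced array). Some arrays of different groups thus deviated together. The labels name no batch, and a batch under other numbers was not modelled.

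Leaving out 1 array gave 0 to 4 genes for A1 against U and 0 to 8 for A3 against A2. The ranges were 3311 to 3526 for the hairpin at 84 h, 3601 to 3690 against A5M, 434 to 579 for A5M, 2630 to 2758 at 72 h, 1780 to 1923 in Su-DHL1, 4455 to 4676 in the hairpin average, 202 to 258 between the lines, 78 to 122 between the times, 2386 to 2626 and 2407 to 2646 for A2 and A3 against A1, 2545 to 2734 and 2449 to 2622 against U, 2780 to 3159 in the inhibitor average and 1568 to 1819 shared. A lone pair of arrays was taken to vary like the other groups. Lists left without members under the 60th percentile filter gave no value. Signals near the added 11 limit the size of large folds.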

Other observations

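The tests that weigh explanations of the G2/M and ATF4 genes, and the alternatives with the ACTB ratio, were chosen only after the results were seen, and the counts of splits were set before. Several gene groups not described in the report were tested with the ALK hairpin. Of 35 interferon response genes 18 rose and 4 fell (20 and 4 adjusted over the list alone, median 0.31, camera adjusted p = 0.0275), led by IFIT1 (2.57) and TRIM22 (1.02), a call lost at adjusted p = 0.197 with an estimated correlation (0.0106 to 0.197 over the alternatives). Genes of glycolysis and hypoxia fell in 12 of 27 cases and rose in 2 (12 and 2 adjusted over the list alone, median -0.13, camera adjusted p = 0.0147), with the kinase genes PDK1 at -1.01 and HK2 at -0.83. That call was lost at adjusted p = 0.190 with an estimated correlation, and with A5M cells as the 84 h control the median was -0.01 (adjusted p = 0.601, and between 0.00551 and 0.601 over the alternatives). Of 19 BCL2 family and apoptosis genes 9 rose and 4 fell (10 and 4 adjusted over the list alone, median 0.17, camera adjusted p = 0.448): BIRC5 (-1.61) and BCL2A1 fell, while FAS (1.17) and BCL2L1 (0.79) rose. FOXO targets rose in 12 of 21 cases and fell in 4 (13 and 4 adjusted over the list alone, median 0.37, camera adjusted p = 0.139), with TXNIP at 2.22. Cholesterol synthesis genes fell in 9 of 16 cases and rose in 3 (9 and 3 adjusted over the list alone, median -0.21, camera adjusted p = 0.0838), with HSD17B7 at -1.73 and LSS at 1.57. Of 28 ATF4 genes 9 fell and 5 rose (9 and 5 adjusted over the list alone, median -0.06, camera adjusted p = 0.0838). With A5M cells as the 84 h control the ATF4 list was called at -0.22 (adjusted p = 0.00352, and between 0.00352 and 0.255 over the alternatives) and the cholesterol list at -0.24 (adjusted p = 0.0357, and between 0.0357 and 0.213 over the alternatives). Both were also called with no filter, and the ATF4 list with the ACTB ratio as a covariate. For NF-kB targets (8 higher and 5 lower of 21, 8 and 5 adjusted over the list alone) the median of 0.11 and mean of 0.04 were positive and the test's direction was down (camera adjusted p = 0.918), with NFKBIA at -1.62 and MMP9 at 1.48. For T-cell genes (3 higher and 3 lower of 17, 3 and 3 adjusted over the list alone) the median was 0.15, the mean -0.01 and the test down (camera adjusted p = 0.763), with the transcription factor gene LEF1 at -2.03. Epithelial and stromal markers were higher in 2 of 7 cases (2 adjusted over the list alone, median 0.10, camera adjusted p = 0.468). Limma called 0 of 7 B-cell markers, 0 of them with an unadjusted p under 0.05 (median -0.05, camera adjusted p = 0.763).

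After A2 and A3, NF-kB targets fell in 5 of 21 cases and rose in 2 (5 and 2 adjusted over the list alone, median -0.20, camera adjusted p = 0.00997), with the adhesion molecule gene ICAM1 at -1.84, a call lost at adjusted p = 0.170 with an estimated correlation (0.00424 to 0.170 over the alternatives). Genes of glycolysis and hypoxia were mixed, 10 higher and 7 lower of 27 (11 and 7 adjusted over the list alone), with the glucose transporter gene SLC2A3 at -2.74 and ENO2 at 1.62, and the median of 0.08 differed in sign from the mean of -0.04 and the test (camera adjusted p = 0.967). BCL2 family genes had 6 higher and 6 lower of 19 (6 and 6 adjusted over the list alone), with a median of 0.15 against a mean of -0.11 and a downward test (camera adjusted p = 0.762). Of 16 p53 targets 9 rose and 4 fell (9 and 4 adjusted over the list alone, median 0.37, camera adjusted p = 0.356), with DDB2 at 1.91 and AEN at -1.92. FOXO targets had 7 higher and 6 lower of 20 (7 and 6 adjusted over the list alone, median 0.15, camera adjusted p = 0.627), among them the cell cycle inhibitor CDKN1B (1.84). Cholesterol synthesis genes rose in 6 of 15 cases and fell in 2 (7 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.315). Heat shock genes fell in 6 of 14 cases and rose in 1 (6 and 1 adjusted over the list alone, median -0.15, camera adjusted p = 0.128), and with U in place of A1 the list was called at -0.31 (adjusted p = 0.0264, and between 0.0264 and 0.384 over the alternatives). Interferon genes rose in 7 of 33 cases and fell in 4 (7 and 4 adjusted over the list alone, median 0.04, camera adjusted p = 0.762), and MHC class II rose in 3 of 10 (3 adjusted over the list alone, median 0.27, camera adjusted p = 0.328). T-cell genes had 2 higher and 3 lower of 16 (2 and 3 adjusted over the list alone, median -0.14, camera adjusted p = 0.328), and myeloid markers 2 lower of 5 (2 adjusted over the list alone, median -0.30, camera adjusted p = 0.0971). Of 6 epithelial and stromal markers limma called 1 lower over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 (median -0.06, camera adjusted p = 0.731). It called 0 of 6 B-cell markers, 0 of them with an unadjusted p under 0.05 (median -0.15, camera adjusted p = 0.695).

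Some genes went opposite ways with the hairpin and with the inhibitors, and those named here were chosen after their values were seen. PHLDA1 (2.83 and -2.49), the chemokine receptor CCR1 (2.22 and -2.79), TRIB2 (1.94 and -2.46) and the transcription factor gene ETV1 (1.63 and -2.69) rose with the hairpin and fell with the inhibitors. MXD3 (-1.57 and 2.61) and CDC25C (-1.50 and 1.41) did the reverse. The knockdown lasted 72 or 84 h and the inhibition 6 h, so the method and the duration differ together. The hairpin average also includes Su-DHL1 cells, which were not given the inhibitors here.

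Genes of G2/M were higher 6 h after the inhibitors, with a median of 0.57. With the ACTB ratio as a covariate the median was 0.59 (camera adjusted p = 3.12e-11). As the slope of that covariate comes from the scatter within groups, it cannot exclude RNA quality that differs between the groups. The median less that of all genes was 0.54 before quantile normalization and 0.55 after it (camera adjusted p = 1.97e-13 after it). A scale factor per array moves all genes nearly alike and is taken out of both values, so they cannot test it. They show a rise relative to the other genes, and neither can show a global change of RNA content. The state of the A1 cultures is argued against, as the median against U was 0.66 (adjusted p = 9.53e-14, and between 6.18e-17 and 0.00236 over all alternatives of this list). A change of the mitotic genes soon after ALK inhibition may be biological, a hypothesis from the same data, and its cause was not tested.

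Genes of the ATF4 response were higher in A1 than in U, with a median of 0.46. A single aberrant array is argued against, since the lowest median without 1 of the 6 arrays was 0.43. The median was 0.47 with the ACTB ratio as a covariate (camera adjusted p = 3.30e-27, and between 9.47e-34 and 1.15e-04 over the alternatives). That covariate likewise rests on the scatter within groups and cannot exclude RNA quality that differs between them. Exposure to any of the 3 compounds might raise these genes, and the higher of the medians of A2 and A3 against U was 0.088 (adjusted p = 0.467). It cannot be told apart from an action of A1 alone, because a loss of ALK activity that lowers these genes could offset such a rise in A2 and A3. With the ALK hairpin at 84 h the list median was -0.27 against uninduced cells (camera adjusted p = 0.00368, lost at adjusted p = 0.0508 with an estimated correlation, and between 7.94e-04 and 0.0508 over the alternatives), -0.75 against A5M, which was itself higher by 0.34, and at 72 h -0.02 in TS cells and 0.12 in Su-DHL1 cells, where the test's direction was down, neither called.

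Splits of the arrays gave these counts. Comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05. Of these, 1 of the 10 splits, the real one, gave as many genes for the ALK hairpin against uninduced cells in TS at 84 h (3699, highest other 1), in TS at 72 h (3108, highest other 1) and in Su-DHL1 (2238, highest other 4), and for A5M against uninduced A5 (636, highest other 8). The same share held for A3 against U (2893, highest other 1) and A3 against A2 (13, highest other 2). In the hairpin against A5M (3942), A2 against A1 (2871), A3 against A1 (2808) and A2 against U (3017), limma called 0 genes in each other split, where up to 900, 441, 462 and 377 genes had an unadjusted p under 0.05. For A1 against U 2 of the 10 splits gave 3 genes or more, and the other of them gave 8. For the hairpin average 1 of 100 splits drawn gave as many as 4622 genes, with 1643 the highest other, and for the inhibitor average 1 of 84 gave as many as 3286, with 1 the highest other. The shared calls numbered 1814 in the real split and 0 by limma in each other split, where up to 235 shared genes had an unadjusted p under 0.05. As no other split of the inhibitor arrays called over 1 gene, hardly any call could be shared, so these splits decide nothing about the shared count. For the hairpin average and the inhibitor average, a chance assignment of these arrays is excluded at 0.05. Chance differences between cultures are not, since the labels do not say that replicates are separate cultures.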
